A study of Rattus norvegicus with 3 samples.

How the data were processed

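The series holds 3 single-nucleus RNA libraries from nucleus accumbens punches of outbred Wistar rats, made with the Chromium 3' kit of chemistry 3.1, per the labels' protocols. Each library pooled 5 hemispheres, and the groups were low anxiety, high anxiety and high anxiety with urolithin A. The deposited matrices hold counts of unique molecular identifiers (UMIs) per feature and barcode, made with Cell Ranger 7.1.0, per the file headers. Reads were assigned to the rat build mRatBN7.2, per the submitters' processing notes. The lowest barcode total was above 500 UMIs, so empty droplets had been left out before deposit, and whether free RNA was removed is not given in the sources used here. The files used here gave no clusters or cell names, so the clusters below were rebuilt from the counts. The tables list 23098 features, of which 1814 have no symbol, and 194 symbols sit on several identifiers and were kept apart. Of 661 symbols in the lists fixed before the files were seen, 620 matched.

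Nuclei with at least 500 genes and at most 5% mitochondrial UMIs were kept: 3476 of 3619 in low anxiety, 3810 of 4066 in high anxiety and 3520 of 3739 in urolithin A. Doublets were scored within each library by the Scrublet method of scanpy 1.11.5, and the highest scores, 0.8% per 1000 nuclei, were removed (97, 116 and 99 nuclei). Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes were chosen by their mean rank over libraries, and values were centred and scaled within each library and clipped at 10. From 30 principal components and 15 exact nearest neighbours, Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 7) gave 27 clusters. A cluster took the name of the marker list, of 16, with the highest mean log2 fold against all other clusters, given at least 3 members at least 2-fold higher, each with at least 20 UMIs and 10 CPM (UMIs scaled to the total). Clusters that met this for no list, whose 10 leading genes held more markers of another class, or with few UMIs per nucleus and no marker among those genes, stayed unnamed. Medium spiny neuron clusters took the subclass with the highest mean. These limits within the naming rule were set after the files were seen. All names rest on these rebuilt clusters. D1 neurons came from clusters 1 and 3 and D2 neurons from clusters 2 and 7, in every library. The D1 name of cluster 3 was the weaker, with a mean log2 fold of D1 markers of 0.235, against 1.01 in cluster 1. Its highest list was that shared by medium spiny neurons, at 0.782, and 0 D1 markers were among its 10 leading genes. Other tools were python 3.11.15, anndata 0.12.19, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

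Counts were summed over the nuclei of each class and library and scaled to the class total (CPM). A gene was measured in a comparison if it had at least 100 UMIs in 1 of the 2 libraries. The classes fixed for comparison were compared where each library held at least 100 nuclei: D1 and D2 medium spiny neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors and microglia. GABAergic interneurons fell below that number in low anxiety, and eccentric medium spiny neurons were not among the classes fixed for comparison by gene. With 1 library per group, no test and no p-value was made, and cells were not used as replicates. Genes were counted by a fixed rule of 1.5-fold, and list members by a rule of 1.25-fold, higher or lower. Ratios have exact conditional 95% intervals (Clopper-Pearson), and shares of nuclei have exact binomial 95% intervals. UMIs of 1 nucleus are not independent draws from an animal, so intervals cover counting error only. A count of 0 was given a floor of 3 counts. The number of genes past 1.5-fold expected from counting was the mean of 100 draws from equal proportions.

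For each of 29 gene lists the median log2 ratio of the measured members was taken, with an interval from 1000 Poisson redraws and its percentile among 10000 random lists drawn from the 100 genes nearest in abundance to each member. The percentile describes the list and is no test. List medians were kept in glial classes only with at least 4 members measured, a minimum chosen after the data were seen. The 2 main comparisons were high anxiety over low anxiety and urolithin A over high anxiety, with urolithin A over low anxiety beside them. Because the high anxiety library is in both, their correlation, covariance and shared genes are given beside values from redraws without a difference.

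The genes named were fixed by rule before the files were seen: in medium spiny neurons the 5 highest and 5 lowest ratios of measured genes with a symbol in each main comparison, in glial classes the 2 highest and 2 lowest, in each list the 4 members furthest from 0, the 5 genes furthest in opposite directions, and genes fixed by name, among them Fkbp5, Ppargc1a, Pink1 and the sex-linked genes. Not every gene that the rule picks is named in the text. Leading genes of a cluster are named where they describe it, and other genes are named only in the closing section, which says so. Ddx3y had 0 UMIs in every class and library and Usp9y at most 4.

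The gene step was tested on simulated D1 counts for high anxiety over low anxiety. Among 7403 genes, with 50 at each fold, 2% of genes at 1.25-fold passed 1.5-fold, 50% at 1.5-fold, 98% at 2-fold and 100% at 3-fold, and 0.153% of unchanged genes did. Intervals held the true ratio for 95.1% of unchanged genes. The simulated counts held counting error alone, so this does not test spread between nuclei, animals or libraries. A list shifted by 0.4 returned a median of 0.39. For the 2 ratios that share a library, simulated data without an effect gave a covariance of -0.0073 against -0.00714 in redraws, and a planted -0.04 gave -0.0457.

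Alternatives changed the nucleus filter (none, or at least 1000 genes and at most 1% mitochondrial UMIs), doublet removal, centring, cluster resolution (0.5 and 2), the minimum of UMIs (30 and 200), the scaling (median of ratios, the trimmed mean of M values of edgeR 4.0.16 in R 4.3.3, or totals without mitochondrially encoded genes), thinning to the smallest total, and means over nuclei. An equal mix of subclusters and the largest subcluster alone were added after the data were seen, for D1 and D2 neurons. The reference table for gene names followed another rat assembly and was not used, and raw reads and behaviour scores were not analysed here.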

Results

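Single-nucleus RNA sequencing measured the transcripts of nuclei from nucleus accumbens punches of outbred Wistar rats that had been classed by behaviour in the elevated plus maze, the open field and a test with a new object. There were 3 groups with 1 library each: low anxiety, high anxiety, and high anxiety after 2 months of urolithin A, a gut microbial metabolite of ellagitannins that is known to induce mitophagy. Each library pooled punches from 5 hemispheres at 16 weeks of age. With 1 library per group there were no replicates, so every difference below is a difference between 2 libraries, and every interval is a 95% interval for counting error only. The deposited tables held 3619 barcodes and 16728049 unique molecular identifiers (UMIs) for low anxiety, 4066 barcodes and 22095390 UMIs for high anxiety, and 3739 barcodes and 19162530 UMIs for urolithin A. After filtering and removal of likely doublets, 3379, 3694 and 3421 nuclei remained in that order, with medians of 3952, 4549.5 and 4726 UMIs and 2201, 2391.5 and 2498 genes per nucleus. All 3 libraries carried Y-linked transcripts: Uty had 625, 686 and 672 UMIs in the D1 medium spiny neurons defined below, and Kdm5d had 253, 290 and 291.

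Nuclei were grouped into clusters and the clusters named by fixed marker genes, so each class is marker-defined and -like: D1 medium spiny neuron-like, astrocyte-like, and so on, written below without the suffix. D1 medium spiny neurons, which express the dopamine receptor Drd1 and feed the direct pathway, made up 22.3% of nuclei in low anxiety (20.9% to 23.8%), 17.8% in high anxiety (16.5% to 19.0%) and 22.0% in urolithin A (20.6% to 23.4%). D2 medium spiny neurons of the indirect pathway made up 16.5% (15.2% to 17.7%), 13.7% (12.6% to 14.9%) and 15.6% (14.4% to 16.8%). Oligodendrocytes stood at 20.8% in low anxiety (19.5% to 22.2%), 28.2% in high anxiety (26.8% to 29.7%) and 27.0% in urolithin A (25.6% to 28.6%). Astrocytes were highest in low anxiety, at 6.63% (5.81% to 7.52%), 3.76% (3.17% to 4.43%) and 3.63% (3.02% to 4.31%). Microglia made up 6.01% (5.23% to 6.86%), 7.01% (6.21% to 7.88%) and 4.94% (4.24% to 5.72%), and oligodendrocyte precursors 3.88% (3.25% to 4.58%), 3.52% (2.95% to 4.17%) and 4.03% (3.4% to 4.75%). Most of these orders did not hold in nuclei with at least 1000 genes and at most 1% mitochondrial UMIs, called the stricter nucleus filter below. There D1 neurons were 30.2%, 19.8% and 24.9%, D2 neurons 24.5%, 17.7% and 17.4%, oligodendrocytes 9.41%, 17.9% and 21.1%, astrocytes 5.94%, 5.85% and 6.45%, microglia 2.91%, 7.09% and 5.30%, and precursors 3.59%, 5.17% and 4.28%.

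Eccentric medium spiny neurons, a group apart from the classical D1 and D2 classes, were 10.7% of low anxiety nuclei (9.69% to 11.8%), 8.55% of high anxiety nuclei (7.67% to 9.50%) and 6.81% of urolithin A nuclei (5.99% to 7.71%). One of their 3 clusters, number 16, held 104 low anxiety nuclei against 11 and 16 in the other libraries, so it may be a feature of that library and not a cell type. GABAergic interneurons made up 2.43% (1.94% to 3.003%), 3.09% (2.55% to 3.70%) and 4.06% (3.43% to 4.78%), but 5.94%, 5.54% and 7.89% under the stricter filter. Cholinergic interneurons were scarce, at 15, 18 and 26 nuclei, as were committed oligodendrocyte precursors at 16, 36 and 27. Glutamatergic neurons, which the accumbens itself is not known to hold and which its neighbours do, made up 2.93% (2.39% to 3.56%), 5.36% (4.66% to 6.14%) and 0.614% (0.380% to 0.937%). Neuroblasts, in a cluster led by cell cycle genes such as Top2a and Cenpf, made up 1.154% (0.822% to 1.57%), 3.06% (2.53% to 3.67%) and 0.146% (0.047% to 0.341%). Without the nucleus filter they were 2.19%, 3.99% and 0.414%, and under the stricter filter no cluster took that name. Clusters without a name held 5.74%, 4.47% and 9.65% of nuclei. A share of nuclei also moves with the tissue a punch took and with depth, and the low anxiety library had the fewest UMIs per nucleus.

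**Figure D1:**
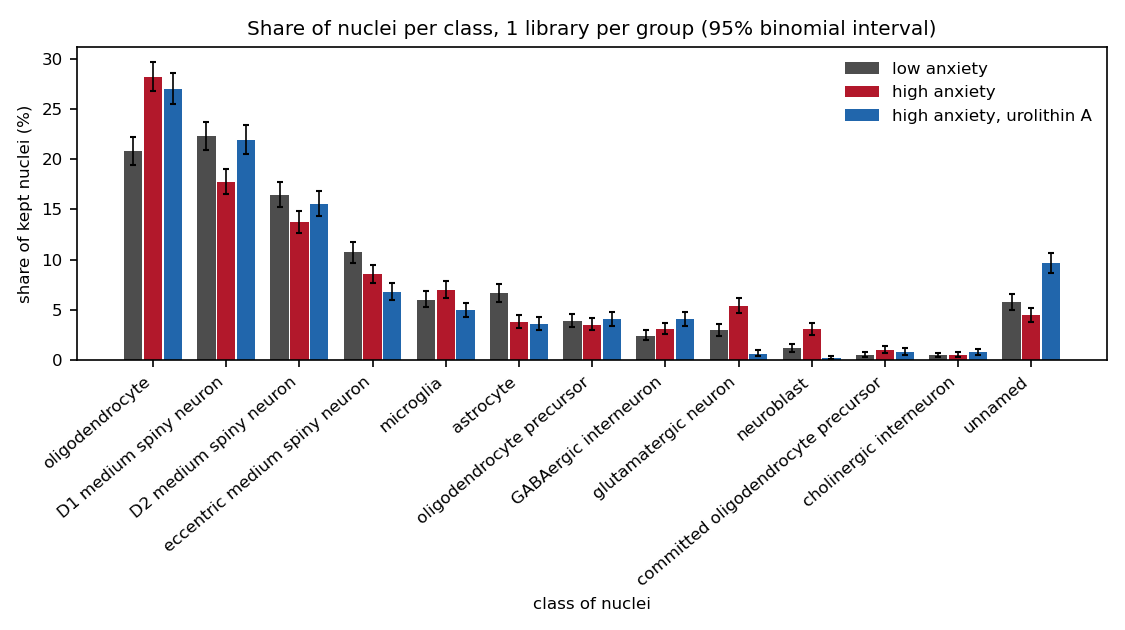
Percent of kept nuclei (vertical axis) in each marker-defined class (horizontal axis) for the 3 libraries. Bars give the share and whiskers the 95% interval of counting error. Oligodendrocytes stood at 28.2% in high anxiety against 20.8% in low anxiety, and astrocytes at 3.76% against 6.63%.

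High anxiety was first compared with low anxiety in D1 medium spiny neurons, to ask which transcripts differ in the accumbens of rats that differ in anxiety. The cell adhesion gene Ctnna3, which encodes alpha-T-catenin, was higher in high anxiety (log2 ratio 1.49, 1.37 to 1.60), at 179, 502 and 404 CPM, the UMIs scaled to the class total, in low anxiety, high anxiety and urolithin A. Vit, which encodes vitrin of the extracellular matrix, was the gene with the largest positive ratio (1.85, 1.28 to 2.46), followed by Ada, which encodes adenosine deaminase (1.81, 1.29 to 2.36), Gm17606 (1.49, 1.21 to 1.78) and Bche, which encodes butyrylcholinesterase (1.37, 0.82 to 1.95). Lowest was Snapin, whose product binds the SNARE complex of vesicle release (-1.37, -1.67 to -1.07), at 64.1, 24.9 and 44 CPM in the same order. Next came Srm, which encodes spermidine synthase (-1.36, -1.85 to -0.87), the secreted synaptic organiser Sparcl1 (-1.28, -1.67 to -0.91), the stress kinase gene Map2k7 (-1.25, -1.67 to -0.84) and Dlk1, a Notch ligand-like gene (-1.24, -1.59 to -0.89). Of 7457 genes measured in these neurons, 166 lay at least 1.5-fold higher and 206 at least 1.5-fold lower, where redraws of the counts from identical means gave 4.69 and 2.92 on average. The median D1 nucleus held 6026.5 UMIs in low anxiety, 7678.5 in high anxiety and 6672 in urolithin A, and no replicate stood behind any of these differences. The stricter nucleus filter left 104 genes higher, and Vit was at 1.06 within the largest D1 cluster.

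D2 medium spiny neurons of high anxiety also had more Gm17606 (1.57, 1.23 to 1.92) and Ctnna3 (1.47, 1.33 to 1.60) than those of low anxiety. Tspan4, a tetraspanin gene (1.33, 1.00 to 1.68), Ddo, which encodes D-aspartate oxidase (1.24, 0.70 to 1.81), and the cytoskeletal collapsin response mediator gene Dpysl3 (1.22, 0.93 to 1.52) completed the 5 highest. Abhd14a (-1.24, -1.66 to -0.84), Tmem145 (-1.20, -1.71 to -0.71), the copine gene Cpne7 (-1.10, -1.58 to -0.64), Haghl (-1.10, -1.40 to -0.80) and the kinase gene Mast4 (-1.10, -1.59 to -0.61) were the 5 lowest. In all, 114 of 6266 measured genes were at least 1.5-fold higher and 154 at least 1.5-fold lower, against 4.98 and 3.08 from counting alone. D2 nuclei held medians of 5703, 7263 and 6392 UMIs in low anxiety, high anxiety and urolithin A, and here too the difference had no replicate check. Within the largest D2 cluster 92 genes were lower.

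Transcripts encoded by the mitochondrial genome, which cover subunits of the respiratory chain and of ATP synthase, were higher in high anxiety in both neuron classes. In D1 neurons the list had a median log2 ratio of 0.35 (0.30 to 0.41), with 6 of 11 measured members higher and 0 lower by the fold rule for list members given above, which holds for all lists below. Mt-nd3 (1.22, 1.04 to 1.40) and Mt-nd4l (1.146, 0.94 to 1.36) stood highest, with Mt-nd1 at 0.54 and Mt-atp6 at 0.53. In D2 neurons the median was 0.38 (0.31 to 0.45), with 7 of 11 higher and 0 lower, led by Mt-nd3 (1.14, 0.90 to 1.38) and Mt-nd4l (1.01, 0.75 to 1.27). Both medians lay at the 100th percentile of 10000 random lists of matched abundance. The share of UMIs from these genes was 0.835% in low anxiety D1 neurons, 1.00% in high anxiety and 1.12% in urolithin A, and 0.686%, 0.847% and 1.10% in D2 neurons. With nuclei limited to at most 1% mitochondrial UMIs, a filter that acts on the measured quantity itself, the D2 median moved to 0.15. Under that filter neurons fell into clusters by library: 1 D2 cluster held 431 low anxiety nuclei against 3 in each other library and the other 6 against 339 and 286, and the 4 D1 clusters split in the same way. This holds for all neuron values under the stricter nucleus filter below. Oligodendrocyte markers, from the class with the highest mitochondrial share, stood beside the list at 160, 211 and 204 CPM in D1 neurons and 167, 199 and 206 CPM in D2 neurons of the 3 libraries.

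Nuclear genes for the same respiratory complexes stayed near their total. Nuclear-encoded subunits of oxidative phosphorylation had a median of -0.00 (-0.05 to 0.05) in D1 neurons, with 1 of 67 higher and 3 lower, among them Ndufc1 (-0.56, -0.75 to -0.38) and Ndufs7 (-0.41, -0.67 to -0.15). The D2 median was -0.05 (-0.09 to 0.02), with 1 of 59 higher and 4 lower, including Ndufc1 at -0.56 and Cyc1 at -0.52. Mitochondrial ribosomal protein genes leaned lower in D1 neurons, at -0.16 (-0.23 to -0.04), with 12 of 36 lower, led by Mrpl17 (-0.98, -1.28 to -0.69) and Mrps26 (-0.94, -1.24 to -0.65), and 1 higher. That median turned to 0.01 under the stricter nucleus filter and to 0.02 when genes needed 200 UMIs. Its D2 counterpart was -0.07 (-0.19 to 0.03) (0.03 under the stricter filter), with 2 of 23 higher and 7 lower, Mrpl58 at -0.95 and Mrpl17 at -0.93.

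Among the lists of mitochondrial upkeep, mitophagy and autophagy genes stood at 0.00 (-0.09 to 0.07) in D1 neurons with 2 of 20 higher and 2 lower. Bnip3, a mitophagy receptor (0.50, 0.05 to 0.96), and Gabarapl1 (0.37, 0.10 to 0.63) were higher, while Phb2 (-0.47, -0.88 to -0.06) and Fkbp8 (-0.39, -0.62 to -0.15) were lower. In D2 neurons the same list had a median of 0.02, with Usp30 at 0.41 and Fkbp8 at -0.51. The mitophagy kinase gene Pink1 had only 16, 17 and 18 UMIs in D1 neurons of the 3 libraries. Genes of mitochondrial fusion, fission, cristae and transport had medians of -0.00 in D1 and 0.01 in D2, where Mfn2 was at -0.33 in D1 and Samm50 at -0.44 in D2. Protein import genes had medians of 0.02 and 0.03, with Timm22 at 0.51 in D1. Biogenesis genes had medians of 0.08 (0.18 under the stricter filter) and 0.09, and their co-activator Ppargc1a stood at 0.08 (0.03 to 0.13) in D1 and 0.02 (-0.05 to 0.08) in D2. The D1 value of Ppargc1a turned to -0.03 within the largest D1 cluster.

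Mitochondrial calcium and VDAC genes were at 0.13 (0.04 to 0.25) in D1, with Vdac3 (0.53, 0.27 to 0.80) and Vdac1 (0.33, 0.13 to 0.52) among 3 of 9 counted higher, and at 0.04 in D2. Antioxidant genes were at 0.01 and 0.12, with Gpx4 lower in D1 (-0.43, -0.69 to -0.17) and D2 (-0.53, -0.86 to -0.21). Tricarboxylic acid cycle and pyruvate dehydrogenase genes had medians of 0.01 and -0.03 (-0.157 when genes needed 200 UMIs), with Pdha1 higher in both (0.84 in D1 and 0.48 in D2). Glycolysis genes had medians of -0.08 and 0.01, with Ldha at 0.39 in D1 and Pgam1 at 0.48 in D2.

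Signalling genes of the striatum were read as fixed lists. The list of dopamine, opioid and striatal signalling had a D1 median of 0.12 (0.05 to 0.16), with 3 of 20 higher and 2 lower, and a D2 median of 0.11 (0.05 to 0.16), with 1 of 17 higher and 0 lower. Within the largest D1 cluster the D1 median was 0.0445. Oprd1, the delta opioid receptor, was higher in D1 (0.85, 0.42 to 1.29) and D2 (0.36, 0.21 to 0.51), although the D1 value was -0.47 within the largest D1 cluster. The cannabinoid receptor gene Cnr1 (0.54, 0.11 to 0.98) was also higher in D1, while Penk, the enkephalin precursor, was lower (-0.59, -0.88 to -0.30). Potassium channel genes had medians of 0.05 (0.00 to 0.10) in D1 and 0.08 (0.03 to 0.12) in D2, with Kcna4 at 0.41 and 0.55. Glutamate receptor genes had medians of 0.04 (-0.01 to 0.05) and 0.08 (0.04 to 0.11) (0.02 within the largest D2 cluster), with 0 of 20 and 0 of 19 higher, and Gria4 at 0.30 in D2. GABA-A receptor and gephyrin genes leaned the other way, at -0.13 (-0.18 to -0.05) in D1 and -0.09 (-0.12 to 0.02) in D2, with Gabrg1 (-0.53, -0.78 to -0.28) the member counted lower in D1 and Gabrd (-0.39, -0.59 to -0.18) in D2.

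Postsynaptic density and adhesion genes stayed near their total, at 0.01 (-0.01 to 0.07) in D1 and 0.04 (-0.01 to 0.07) in D2, although the scaffold gene Shank3 was higher in both (0.42, 0.28 to 0.56 and 0.39, 0.23 to 0.54), Lrrtm2 was higher in D1 (0.63, 0.18 to 1.09) and Nlgn3 lower (-0.49, -0.87 to -0.10). Presynaptic release genes had medians of 0.01 and -0.01, with the vesicle SNARE gene Vamp2 lower in D1 (-0.88, -1.16 to -0.59) and D2 (-0.86, -1.19 to -0.53). Ventral striatum and shell markers were lower, at -0.46 (-0.55 to -0.40) in D1 with 4 of 5 lower, and -0.25 (-0.37 to -0.16) in D2 with 2 of 4, and at -0.717 and -0.38 under the stricter nucleus filter. Their members included Wfs1 (-0.62, -0.73 to -0.51 in D1 and -0.60, -0.77 to -0.44 in D2), Cartpt, the precursor of the CART peptide (-0.46, -0.54 to -0.38 and -0.41, -0.50 to -0.33), and the neurotensin gene Nts (-0.36 in D1). Dorsal striatum markers went both ways in D1 neurons, at -0.07 (-0.24 to 0.05), but -0.33 under the stricter filter and 0.0544 with an equal mix of the D1 clusters, with Cnr1 higher and Coch (-0.33) lower.

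Stress and housekeeping lists showed small shifts. Glucocorticoid-responsive genes had medians of 0.15 (0.01 to 0.29) in D1 and 0.15 (0.02 to 0.28) in D2, with Errfi1 at 0.41 in D1 and Fkbp5, which restrains the glucocorticoid receptor, at 0.15 (-0.08 to 0.38) in D1 and 0.12 (-0.15 to 0.38) in D2. Heat shock genes were at 0.18 (0.04 to 0.26) in D1 and 0.07 (-0.13 to 0.21) in D2, with the constitutive chaperone gene Hspa8 lower in D1 (-0.53) and Hsp90aa1 higher (0.30). Cytosolic ribosomal protein genes had a D1 median of 0.13 (0.07 to 0.21), with 18 of 60 higher, 6 lower, Rpl5 at 0.59 and Rpl37 at -0.64, and a D2 median of 0.03 (-0.03 to 0.13) (0.23 when genes needed 200 UMIs). Circadian clock genes were at 0.09 and 0.06, with Dbp lower in D1 (-0.40) and Cry1 higher in D2 (1.04, 0.55 to 1.56). Immediate early genes were scarce, with Nr4a3 (0.68, 0.25 to 1.12) and Nr4a1 (0.38, -0.01 to 0.78) the 2 measured in D1. Of the major histocompatibility complex, only RT1-T24-3 was measured in both neuron classes, and it was higher in D1 (0.98, 0.82 to 1.13) and D2 (0.89, 0.72 to 1.07). Myelin genes had 3 measured members in D1, with Cnp at 1.16. Inflammation genes also had 3 measured members, with Apoe at -0.79 in D1, where astrocyte markers stood at 644, 762 and 612 CPM. Haemoglobin genes were not measured in either class.

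**Figure D2:**
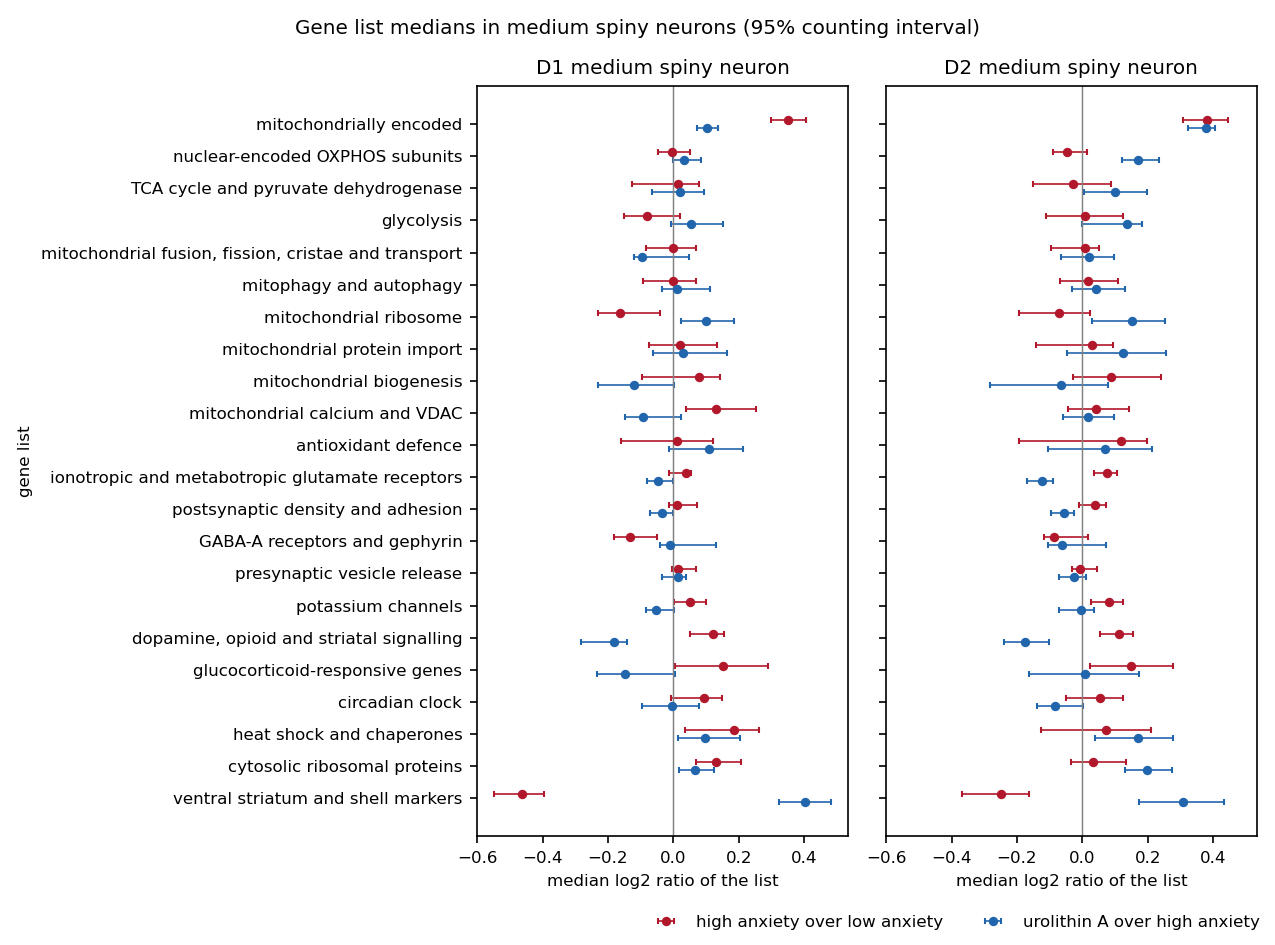
Median log2 ratio (horizontal axis) of each gene list (vertical axis) in D1 neurons (left) and D2 neurons (right), with points for the median and whiskers for its 95% counting interval. Red points compare high anxiety with low anxiety and blue points urolithin A with high anxiety, and the ventral striatum list lies at -0.46 in the first and 0.40 in the second in D1 neurons.

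Urolithin A was then compared with untreated high anxiety, to ask what the compound's 2 months of dosing went with. In D1 neurons the neurokinin B gene Tac3 was the highest (log2 ratio 1.80, 1.62 to 1.99), at 129, 61.5 and 215 CPM in low anxiety, high anxiety and urolithin A. Dlk1 (2.38-fold, log2 interval 0.91 to 1.60), Sparcl1 (1.09, 0.72 to 1.48), the acyltransferase gene Agpat4 (1.046, 0.63 to 1.48) and Chga, which encodes chromogranin A of secretory granules (1.03, 0.91 to 1.14), were the next highest. Pld5 (-1.58, -2.12 to -1.07), the heparan sulfate sulfotransferase gene Hs6st3 (-1.28, -1.47 to -1.09), the Ras exchange factor gene Rasgrf2 (-1.26, -1.58 to -0.94), Rasd2, which encodes the striatal G protein Rhes (-1.07, -1.46 to -0.70), and the phosphatase gene Ptpn13 (-1.047, -1.54 to -0.57) were the lowest. Among 7533 measured genes, 91 were at least 1.5-fold higher and 66 at least 1.5-fold lower, against 3.53 and 3.63 from counting alone. The excess of higher genes was gone with median-of-ratios scaling (72 and 72) and small with the trimmed mean of M values (76 and 70), and the counts were 59 and 42 under the stricter filter and 60 and 29 in the largest D1 cluster. The 2 D1 clusters held 512 and 242 nuclei in low anxiety, 401 and 255 in high anxiety and 544 and 207 in urolithin A, with Dlk1 among the leading genes of the first and Rasgrf2 of the second. Rasgrf2 was at -0.95 with the mix held equal and -0.04 within the largest D1 cluster, and Dlk1 at 1.04 and 0.94. No second library of either group could test these differences.

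In D2 neurons Cntnap4, a neurexin-family adhesion gene (1.53, 1.01 to 2.08), Tac3 (1.40, 0.92 to 1.90), the kinase gene Pnck (1.33, 0.87 to 1.81), Cpne7 (1.21, 0.76 to 1.68) and the calcitonin receptor gene Calcr (1.18, 0.94 to 1.43) were the highest under urolithin A. For Tac3 a single nucleus held 25.5% of its D2 UMIs in high anxiety and another 20.8% in urolithin A, and within the largest D2 cluster its ratio turned to -0.59, where Cntnap4 was at 0.50 and Calcr at 3.26. The lowest were Zfp804b (-1.45, -1.79 to -1.11), the sodium-activated potassium channel gene Kcnt2 (-1.05, -1.44 to -0.68), the muscarinic receptor gene Chrm3 (-1.01, -1.29 to -0.73), the chromatin remodeller gene Chd7 (-0.98, -1.39 to -0.58) and the orphan nuclear receptor gene Esrrg (-0.92, -1.34 to -0.52). In total 106 of 6279 genes were at least 1.5-fold higher and 42 at least 1.5-fold lower, against 3.66 and 4.78 from counting alone. With scaling by the trimmed mean of M values those counts were 75 and 57, so the higher genes were 71.6% of the total in one case and 56.8% in the other, and within the largest D2 cluster they were 53 and 24. The D2 cluster marked by Calcr held 191, 135 and 223 nuclei in low anxiety, high anxiety and urolithin A.

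Mitochondrially encoded transcripts were higher again under urolithin A in D2 neurons, at 0.38 (0.32 to 0.41), with 7 of 11 higher and 0 lower, while cytosolic ribosomal protein genes, also cytoplasmic, were higher too, at 0.20 (0.13 to 0.27). Mt-cyb (0.55, 0.49 to 0.61), Mt-atp6 (0.44, 0.38 to 0.49) and Mt-co3 (0.41, 0.35 to 0.47) were among them. D1 neurons showed a smaller median of 0.10 (0.07 to 0.14), with 0 of 11 higher and 2 lower, namely Mt-nd4l (-0.50, -0.67 to -0.33) and Mt-nd3 (-0.42, -0.57 to -0.27), and Mt-co3 at 0.31. Limiting nuclei to at most 1% mitochondrial UMIs turned the D1 median to -0.13 and moved the D2 median to 0.14, and the D1 median was 0.0583 as a mean over nuclei. Nuclear-encoded subunits of oxidative phosphorylation were higher in D2 neurons, at 0.17 (0.12 to 0.23) with 14 of 60 higher and 0 lower, above 99.98% of matched random lists. Ndufb11 (0.58, 0.15 to 1.02), Atp5f1a (0.51, 0.19 to 0.84), Ndufa8 (0.48, 0.15 to 0.80) and Ndufa11 (0.44, 0.13 to 0.76) led them. In D1 neurons the same list stood at 0.03 (-0.00 to 0.08) with 4 of 67 higher, among them Ndufa11 (0.49, 0.23 to 0.75), and moved to 0.16 without doublet removal and to 0.17 at the lower cluster resolution, and to -0.0056 within the largest D1 cluster.

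Mitochondrial ribosomal protein genes were at 0.10 (0.02 to 0.18) in D1, with 5 of 35 higher and 3 lower and Mrps36 at 0.84, and at 0.15 (0.03 to 0.25) in D2, with 5 of 21 higher and 1 lower and Mrpl57 at 0.73. The stricter nucleus filter turned the D1 value to -0.06. Protein import genes had medians of 0.03 in D1 and 0.13 in D2 (0.22 and -0.08 under the stricter nucleus filter), with the import receptor gene Tomm20 higher in D1 (0.37, 0.28 to 0.45) and D2 (0.48, 0.37 to 0.59). Mitophagy and autophagy genes, the process urolithin A is known for, stayed near their total at 0.01 (-0.03 to 0.11) in D1 and 0.04 (-0.03 to 0.13) in D2. Among them the receptor gene Sqstm1 was at 0.35 in D1 and Map1lc3a at 0.37 in D2. Biogenesis genes had medians of -0.12 and -0.06 (-0.352 in D2 under the stricter filter), and Ppargc1a was lower in D1 (-0.22, -0.28 to -0.17) and D2 (-0.37, -0.44 to -0.30).

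Fusion, fission, cristae and transport genes stood at -0.10 and 0.02 under urolithin A, with Trak2 at -0.23 in D1 and Samm50 at 0.42 in D2. Calcium and VDAC genes were at -0.09 and 0.02, with Letm1 at -0.46 in D2. Antioxidant genes were at 0.11 and 0.07, tricarboxylic acid cycle genes at 0.02 and 0.10, and glycolysis genes at 0.05 and 0.14. Antioxidant genes moved to 0.22 in D1 with doublets left in and in D2 within its largest cluster, and glycolysis genes to -0.02 within the largest D1 cluster. Examples were Prdx4 (0.33 in D1), Dld (0.34 in D2), Tpi1 (0.30 in D1) and the glycolytic enzyme gene Pfkp (-0.34 in D1).

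The median of dopamine, opioid and striatal signalling genes was lower under urolithin A, at -0.18 (-0.28 to -0.14) in D1 with 0 of 20 higher and 7 lower, and at -0.18 (-0.24 to -0.10) in D2 with 1 of 17 higher and 3 lower. The D1 median was -0.12 under the stricter filter, and the D2 median -0.077 with an equal mix of the D2 clusters and -0.266 as a mean over nuclei. In D1 neurons the lower members were led by Rasd2, Oprd1 (-0.92, -1.36 to -0.50), Cnr1 (-0.82, -1.26 to -0.38) and Rasgrp2 (-0.60, -0.76 to -0.44), of which Oprd1 turned to 0.09 within the largest D1 cluster. In D2 neurons the regulator gene Rgs9 (-0.55, -0.64 to -0.46), the phosphodiesterase gene Pde10a (-0.48, -0.53 to -0.44) and the calcium release channel gene Itpr1 (-0.35, -0.43 to -0.26) were lower, and the mu opioid receptor gene Oprm1 was higher (0.36, 0.09 to 0.63). Glutamate receptor genes were at -0.05 (-0.08 to -0.00) in D1, with 1 of 20 higher and 4 lower, and at -0.12 (-0.17 to -0.09) in D2, with 0 of 19 higher and 3 lower. The NMDA receptor subunit gene Grin2a was lower in both (-0.63, -0.74 to -0.54 and -0.50, -0.62 to -0.37) while Grik1 was higher in D1 (0.44). Grm8 stood at -0.45 in D1 and at 0.00 with an equal mix of the D1 clusters.

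Postsynaptic density and adhesion genes had medians of -0.03 (-0.07 to -0.00) in D1 and -0.06 (-0.10 to -0.03) in D2, with Dlgap3 lower in both (-0.27 and -0.36), and Cacng2 at -0.39 in D1, which turned to 0.15 under the stricter nucleus filter. Presynaptic genes had medians of 0.01 and -0.03, with Vamp2 higher in D1 (0.48, 0.19 to 0.78) and D2 (0.47, 0.12 to 0.82). GABA-A receptor and gephyrin genes had medians of -0.01 and -0.06, with Gabrg1 at 0.58 in D1 and Gabra5 at 0.43 in D2. Potassium channel genes had medians of -0.05 (0.00 under the stricter filter) and -0.01, with Kcnip4 at 0.30 and 0.28. Ventral striatum and shell markers were higher, at 0.40 (0.32 to 0.48) in D1 with 3 of 5 higher, and at 0.31 (0.17 to 0.43) in D2 with 2 of 4. Wfs1 (0.71, 0.60 to 0.81 in D1 and 0.75, 0.59 to 0.91 in D2) and Cartpt (0.40, 0.32 to 0.48 and 0.42, 0.34 to 0.50) were among them, while Nts was at -0.07 and -0.33. Dorsal striatum markers had a D1 median of 0.21 (-0.09 to 0.37), with Gpr155 at 0.42 and Cnr1 lower.

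Chaperone genes leaned higher under urolithin A, at 0.10 (0.01 to 0.21) in D1 and 0.17 (0.04 to 0.28) in D2, with the endoplasmic reticulum chaperone gene Hspa5 at 0.41 and 0.50 and Hspa8 at 0.36 and 0.50. Cytosolic ribosomal protein genes were at 0.07 (0.02 to 0.12) in D1 and 0.20 (0.13 to 0.27) in D2, where 15 of 53 were higher and 0 lower, led by Rps3a (0.72) and Rps7 (0.61). The D1 value was 0.26 with doublets left in or at the lower cluster resolution and 0.14 under the stricter filter. Glucocorticoid-responsive genes had medians of -0.15 (-0.23 to 0.01) in D1 and 0.01 (-0.16 to 0.17) in D2, with Fkbp5 at -0.15 (-0.37 to 0.08) and -0.19 (-0.46 to 0.08). Clock genes were at -0.01 and -0.08, with Dbp at 0.20 in D1. Among sparse lists, the immediate early gene Nr4a1 stood at -0.04 in D1, the myelin gene Mbp at 0.22, the inflammation gene Apoe at -0.36 (0.15 at the lower cluster resolution) and RT1-T24-3 at -0.00.

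Across both comparisons, some genes differed one way between the anxiety groups and the other way under urolithin A. In D1 neurons 49 of 7374 genes passed 1.5-fold in opposite directions, 37 of them lower and then higher and 12 higher and then lower, and 0 passed it in the same direction. Only 24 passed it in opposite directions under the stricter nucleus filter and 25 within the largest D1 cluster. Dlk1 (-1.24, then 2.38-fold higher), Sparcl1 (-1.28, then 1.09) and Tac3 (-1.06, then 1.80) were lower and then higher, and Hs6st3 (1.17, then -1.28) and Ptpn13 (1.00, then -1.047) higher and then lower. In D2 neurons 32 of 6167 genes did so, 24 of them lower and then higher and 8 the reverse (16 in all within the largest D2 cluster), among them Cpne7 (-1.10, then 1.21), Pnck (-1.03, then 1.33), Nckap5 (-1.02, then 1.08), Sparcl1 (-1.04, then 0.98) and Ptpro (0.89, then -0.84). The splits of 37 and 12 in D1 and 24 and 8 in D2 were 32 and 13 and 17 and 9 with median-of-ratios scaling, and 34 and 13 and 17 and 10 with the trimmed mean of M values, and were not tested. The high anxiety library stood in both comparisons, so its counting error alone pushes the 2 ratios in opposite directions. Independent lists of these sizes would share 1.65 and 1.49 genes in D1 (lower then higher, and the reverse) and 1.60 and 0.776 in D2, and redraws without any difference gave 0.21 and 0.17 in D1 and 0.33 and 0.30 in D2. The correlation of the 2 log2 ratios was -0.51 over 6780 D1 genes, where redraws gave -0.49, and -0.47 over 5556 D2 genes, where they gave -0.49. Covariances were -0.0258 in D1 against -0.00716 in redraws, a difference of -0.0187, and -0.0239 in D2 against -0.00776, a difference of -0.0162. All or part of this excess may come from the shared library, since anything particular to that library beyond counting error enters both ratios. The redraws and the independent lists hold no spread between libraries, so they give no baseline for it, and this holds for the opposed genes too.

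Set directly against low anxiety, urolithin A neurons had more mitochondrially encoded transcripts, with list medians of 0.45 (0.40 to 0.50) in D1 and 0.77 (0.66 to 0.82) in D2, where all 11 measured members were higher. Under the stricter nucleus filter these medians fell to 0.17 and 0.29. The ventral striatum list stood near the low anxiety level, at 0.01 (-0.11 to 0.14) in D1 and 0.06 (-0.06 to 0.13) in D2. Dopamine, opioid and striatal signalling genes were at -0.18 (-0.21 to -0.09) and -0.11 (-0.16 to -0.02) (in D2 -0.0093 with an equal mix of its clusters and -0.167 under the stricter filter), and nuclear-encoded oxidative phosphorylation genes were at 0.05 (-0.01 to 0.08) in D1 and 0.11 (0.07 to 0.19) in D2. The D1 value of the latter was 0.146 without doublet removal and 0.157 at the lower cluster resolution, and the D2 value 0.0674 under the stricter filter. In D1 neurons 191 of 7497 genes were at least 1.5-fold higher and 92 at least 1.5-fold lower, against 4.76 and 3.01 from counting alone. In D2 neurons the counts were 154 and 74 of 6195, against 4.30 and 3.84, and the stricter filter left 97 higher in D1 and 91 higher in D2. As above, each group was 1 library.

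Mitochondrially encoded genes were also read in glial classes. Astrocytes of high anxiety had less of them than those of low anxiety, at -0.89 (-0.95 to -0.74) with 0 of 8 higher and 8 lower, such as Mt-nd4 (-0.98, -1.19 to -0.76) and Mt-co3 (-0.90, -1.08 to -0.73). The astrocyte median was -0.54 under the stricter nucleus filter and -0.57 with doublets left in, and that of precursors, given next, -0.32 and -0.46. At a cluster resolution of 2 the astrocytes lay largely apart by library, in 1 cluster with 208, 37 and 24 nuclei of low anxiety, high anxiety and urolithin A and another with 16, 102 and 100. Oligodendrocyte precursors were at -0.74 (-0.81 to -0.63) with 8 of 8 lower and Mt-nd2 at -0.83, and microglia at -0.69 (-0.79 to -0.60) with 8 of 8 lower and Mt-co1 at -0.83. Medium spiny neuron markers stood beside them at 1965, 1819 and 1687 CPM in precursors of low anxiety, high anxiety and urolithin A. In microglia they stood at 994, 773 and 861 CPM. The median nucleus held 2834, 3251.5 and 2885.5 UMIs in precursors and 1599, 1889 and 1879 in microglia, in the same order. Oligodendrocytes were at 0.03 (-0.07 to 0.07), but 0.354 without the nucleus filter and -0.155 under the stricter one, with Mt-nd3 at 0.59 and Mt-co3 at -0.32. Under urolithin A against high anxiety, the precursors were higher at 0.79 (0.67 to 0.86) with Mt-atp6 at 1.06 and Mt-cyb at 0.87, a median that turned to -0.15 in nuclei with at most 1% mitochondrial UMIs. Microglia were at 0.31 (0.17 to 0.38), astrocytes at -0.05 (-0.14 to 0.09) and oligodendrocytes at -0.21 (-0.25 to -0.15), and the oligodendrocyte value turned to 0.03 without the nucleus filter. With doublets left in microglia were at 0.15 and astrocytes at 0.24, and microglia were at 0.147 under the stricter filter.

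**Figure D3:**
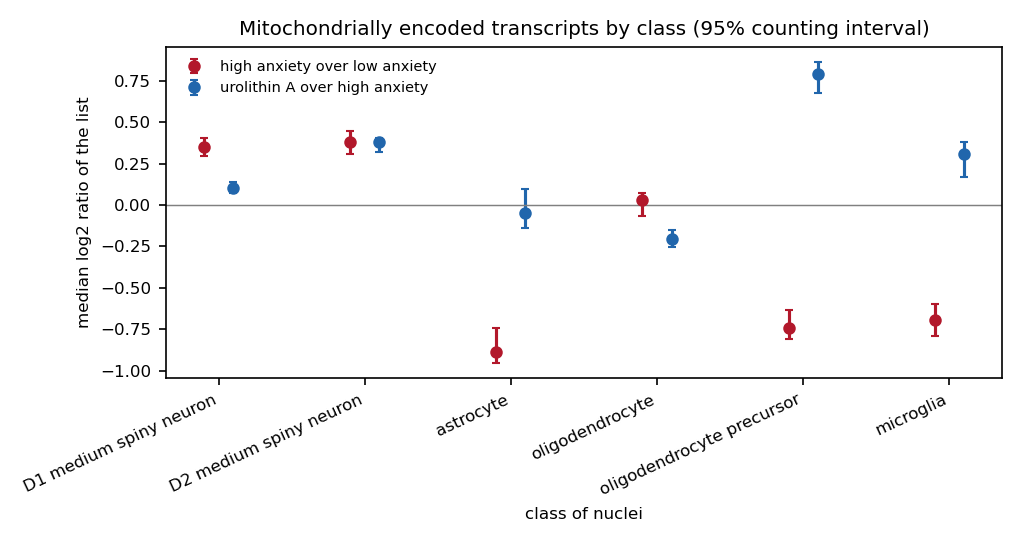
Median log2 ratio of mitochondrially encoded genes (vertical axis) in 6 classes (horizontal axis), with points for the median and whiskers for its 95% counting interval. Red points compare high anxiety with low anxiety and blue points urolithin A with high anxiety. The red points lie at 0.38 in D2 neurons and -0.89 in astrocytes. As a share of UMIs, these genes made up 0.686%, 0.847% and 1.10% in D2 neurons of low anxiety, high anxiety and urolithin A. In astrocytes they made up 1.047%, 0.603% and 0.587%.

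Some genes known from neurons were also lower in astrocytes of high anxiety than in those of low anxiety. The metabotropic glutamate receptor gene Grm7 (-3.31, -4.56 to -2.28, from 8 UMIs in high anxiety) and the synaptic scaffold gene Anks1b (-3.12) were the lowest, and Kdelr3, an endoplasmic reticulum retention receptor gene (1.67), and Efcab3 (1.27) the highest. Potassium channel genes were at -0.62 (-0.85 to -0.37), with Kcnq5 (-2.33) and Kcnip4 (-2.27) lower, and glutamate receptor genes at -0.30 (-0.44 to -0.12), with Grm5 (-1.75) lower. The potassium channel median was -0.142 under the stricter nucleus filter, -0.122 without a filter and -1.29 when thinned, and that of glutamate receptors -0.0833 and -0.0853 with those 2 filters. Medium spiny neuron markers stood beside them at 3135 CPM in low anxiety astrocytes, 1987 in high anxiety and 2024 in urolithin A. Of 982 measured genes, 27 were at least 1.5-fold higher and 63 at least 1.5-fold lower, against 0.73 and 2.86 from counting alone. Those lower fell to 15 under the stricter nucleus filter, and with doublets left in 80 were higher and 172 lower, with Grm7 at -1.45 and Anks1b at -0.77. Under urolithin A against high anxiety, the angiotensinogen gene Agt (0.98) was among the highest and Prpf4b (-0.92) and Fam163a (-0.74) were the lowest, with 14 higher and 20 lower of 728 genes, against 0.69 and 1.87.

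Oligodendrocytes of high anxiety carried more cytosolic ribosomal protein transcripts, at 0.40 (0.35 to 0.50) with 35 of 57 higher and 0 lower, such as Rpl5 (0.88) and Rps16 (0.85). Under urolithin A the list was at -0.13 (-0.19 to -0.07), with 1 of 57 higher and 9 lower. Their myelin genes were at -0.01 (-0.04 to 0.04) (0.279 under the stricter nucleus filter), apart from Mal (0.49), which encodes a proteolipid of compact myelin, and at -0.03 (-0.05 to 0.02) under urolithin A. The lowest genes in high anxiety oligodendrocytes were the neuregulin gene Nrg3 (-1.92) and the synaptotagmin gene Syt1 (-1.47), while Lrfn1 (1.43) and the imprinting regulator Zfp57 (1.41) were the highest. Presynaptic genes were at -0.28 (-0.40 to -0.07) and potassium channel genes at -0.44 (-0.52 to -0.24), of which the latter turned to 0.04 when genes needed 200 UMIs and to 0.0627 without the nucleus filter. Under the stricter filter they were at -3.42 and -3.68, but there oligodendrocytes also lay partly apart by library. One cluster held 77, 9 and 1 nuclei of low anxiety, high anxiety and urolithin A, and another held 13, 176 and 218. The remaining clusters were mixed, with 41, 115 and 97 nuclei and 37, 46 and 34. This holds for all oligodendrocyte values under that filter. There were 130 genes higher and 45 lower of 4600, against 15.06 and 2.00 from counting alone. Thinned to the smallest total 56 were higher, and 102 were lower under the stricter nucleus filter, where Nrg3 was at -4.05 and Syt1 at -4.14. Medium spiny neuron markers as a set were nearly level in oligodendrocytes, at 1669, 1593 and 1514 CPM in low anxiety, high anxiety and urolithin A. Under urolithin A 14 were higher and 28 lower of 4628, against 2.11 and 5.43 (7 and 13 under the stricter filter, where Cd59 was at 0.13), with Vwa1 (1.19) and Cd59 (0.88) the highest and Sp2 (-0.90) and Dlc1 (-0.88) the lowest.

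In oligodendrocyte precursors of high anxiety Ctnna3 (1.59) and RT1-T24-3 (1.37) were the highest and Mt-nd2 and the protocadherin gene Pcdha5 (-0.83) the lowest. The counts were 21 higher and 26 lower of 811 genes (1.83 and 0.84 from counting alone), but 27 and 19 with median-of-ratios scaling, 17 and 35 with the trimmed mean of M values, 33 and 14 under the stricter nucleus filter and 46 and 17 with doublets left in. Under urolithin A the highest were Mt-atp6 and Mt-cyb and the lowest Mtfr2 (-0.71) and Dcaf6 (-0.70), with 22 higher and 7 lower of 831 (1.04 and 1.77), a split that turned to 9 higher and 28 lower under the stricter nucleus filter. Microglia of high anxiety had lower inflammation genes, at -0.46 (-0.64 to -0.29) with 3 of 4 lower and 1 higher. The invariant chain gene Cd74 of antigen presentation (-1.996, -2.53 to -1.48), the complement gene C3 (-0.55) and Apoe (-0.38) were lower and Nfkb1 (1.02) higher, and single nuclei held 37.1% and 36.4% of the Cd74 UMIs in low anxiety and high anxiety. Major histocompatibility complex genes were at 0.10 (-0.11 to 0.18) (-0.168 under the stricter filter), with 1 copy of RT1-CE16 at -0.77, and then at 0.97 under urolithin A. Hs3st2 (1.43) was the highest microglial gene in high anxiety and the transcobalamin gene Tcn2 (-0.98) the second lowest. Microglial counts were 43 higher and 24 lower of 860 (3.19 and 0.33), with an all-gene median of 0.11, and became 33 and 28 with median-of-ratios scaling and 28 and 34 with the trimmed mean of M values. The stricter filter left 8 lower, 43 were lower with doublets left in, and 21 were higher when thinned to the smallest total. Under urolithin A 3 microglial genes were higher and 20 lower of 856 (0.40 and 3.4), but only 2 were lower when thinned to the smallest total and 41 with doublets left in. The highest and lowest included RT1-CE16 and Tmem50a (0.67) upward and Klf12 (-0.89) downward. Glial classes held 124 to 259 nuclei per library outside oligodendrocytes, and no glial difference had a replicate check.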

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

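Of the tests in this part, only the one on a minority of nuclei was chosen before its result was seen. The rules that left the dorsal tissue, 2-gene and D2 cytoplasm tests undecided were set after their values were known. So was the limit placed on the first free RNA test.

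Mitochondrially encoded genes differed in direction between classes under the same comparison. For high anxiety over low anxiety the list medians were 0.35 in D1 neurons and 0.38 in D2 neurons, but -0.89 in astrocytes, -0.74 in oligodendrocyte precursors and -0.69 in microglia, with oligodendrocytes at 0.03 (0.354 without the nucleus filter and -0.155 under the stricter one). For urolithin A over low anxiety they were 0.45 in D1 and 0.77 in D2 neurons, but -0.87 in astrocytes, -0.41 in microglia and -0.28 in oligodendrocytes (0.29 without the nucleus filter), with precursors at 0.05 (-0.365 under the stricter filter and 0.177 without a filter). That astrocyte median was -0.454 with doublets left in and -0.513 under the stricter filter. These differences between classes were not tested, because each group is 1 library.

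A signal also lay outside every named class. Cluster 10, led by an unnamed gene (ENSRNOG00000068611), Spp1, Crh and Galr1, held 2.49% of nuclei in low anxiety, 2.03% in high anxiety and 6.78% in urolithin A, a difference that was not tested.

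The first pattern weighed is the higher mitochondrially encoded transcripts in medium spiny neurons of high anxiety. The test took free RNA shared by all droplets to give 1 sign in every class, and the astrocyte median was -0.89. On values scaled to the class total, a change in free RNA can raise 1 class and lower another, so the sign does not decide. Medium spiny neuron markers were also lower in high anxiety than in low anxiety in astrocytes (1987 against 3135 CPM) and microglia (773 against 994). They were nearer level in precursors (1819 against 1965) and oligodendrocytes (1593 against 1669). Free RNA stays open. A minority of nuclei rich in these transcripts is argued against by the median nucleus, whose mitochondrial share was 1.32 times as high in D2 and 1.39 times as high in D1 neurons. Cytoplasm carried along with nuclei cannot be told apart from a change inside the cells, since cytosolic ribosomal protein genes, at 0.13 in D1, lay between the bounds set for the 2 outcomes, and in D2, at 0.0336 (-0.033 to 0.133), they lay below the lower bound but reached 0.23 with a minimum of 200 UMIs. A difference between anxiety groups stays open and untested, as do differences in dissection or in handling of the 3 pools.

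A second pattern is the genes at least 1.5-fold higher in high anxiety in every class where they were measured, in at least 4 classes. There were 2 such genes of 1133 candidates: Kdelr3, higher in 5 classes by 0.90 to 1.67, and Rims3, higher in 4 classes by 0.94 to 1.155. Free RNA would add similar UMIs per nucleus to each class, and 1 of the 2 genes (Rims3, 4.84 times between classes, against 2.74 for Kdelr3) went past 3 times, which is too few genes to decide. The genotype of the animals pooled cannot be told apart from the group either, because the set holds 2 genes and no variant calls were used. Anxiety itself stays open and untested.

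The third pattern is the lower ventral striatum and shell markers in high anxiety D1 neurons and their higher level under urolithin A. A different mix of D1 clusters 1 and 3 alone does not account for it. With that mix held equal the median was -0.54 for high anxiety over low anxiety and 0.335 for urolithin A over high anxiety. Within the largest D1 cluster the second of these was 0.294. At a cluster resolution of 2 the D1 neurons fell into more clusters, whose mix was not held equal. A shift among such finer groups therefore stays open. Punches that took more dorsal tissue cannot be told apart from the rest, since dorsal markers had a median of -0.075 over members that went both ways, which was -0.33 under the stricter nucleus filter and 0.0544 with the mix held equal. Glutamatergic neurons, not known in the accumbens itself, made up 2.93%, 5.36% and 0.614% of nuclei in low anxiety, high anxiety and urolithin A. Neuroblasts made up 1.154%, 3.06% and 0.146%. Both shares were highest in high anxiety, where the ventral markers were lowest, so a difference in the tissue taken stays open. A shift along the core and shell within the accumbens stays open, as do anxiety and urolithin A, none of which was tested.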

How the results depend on the processing

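The equal subcluster mix and the largest subcluster alone were chosen only after the results were seen. Ratios of genes stayed within their first 95% counting interval in 6672 values, left it in 170 and took the other sign, where that interval left out 0, in 13. List medians did so in 3098, 161 and 14 values, and where the interval held 0 a change of sign was not counted apart. Numbers of genes past 1.5-fold stayed within 1.5 times in 318 values and moved in 100, and shares of nuclei stayed within their interval in 193 and left it in 59. The correlation of the 2 ratios held in all 30 values, from -0.54 to -0.48 in D1 neurons and -0.51 to -0.45 in D2 neurons. In the first comparison the mitochondrially encoded median ran from 0.28 to 0.49 in D1 and from 0.15 to 0.42 in D2 neurons, and in the second from -0.13 to 0.11 and from 0.14 to 0.41. For OXPHOS genes (nuclear-encoded subunits of oxidative phosphorylation) the second comparison ran from -0.01 to 0.17 in D1 and from 0.13 to 0.23 in D2 neurons. Leaving mitochondrially encoded genes out of the totals moved no value, and no centring per library moved 1. Depth limits astrocytes, oligodendrocyte precursors and microglia, where 728 to 982 genes reached the minimum of UMIs in the 2 main comparisons and 515 to 969 in the third. Below, numbers of genes are those at least 1.5-fold higher or lower, and ratios are log2.

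With at least 1000 genes and at most 1% mitochondrial UMIs, D1 neurons had 104 higher (high over low), 59 higher and 42 lower (urolithin A over high), 97 higher (urolithin A over low), 24 opposed. D2 neurons had 91 higher (urolithin A over low). Astrocytes had 15 lower (high over low). Oligodendrocytes had 102 lower (high over low), 7 higher and 13 lower (urolithin A over high). Oligodendrocyte precursors had 33 higher and 14 lower (high over low), 9 higher and 28 lower (urolithin A over high). Microglia had 8 lower (high over low), 5 higher (urolithin A over high). In D1 neurons, high over low, the values were mitochondrially encoded genes 0.28 and mitochondrial ribosome 0.008 (reversed). For urolithin A over high in D1 neurons, the values were mitochondrially encoded genes -0.13 (reversed), mitochondrial ribosome -0.0588 (reversed) and Cacng2 0.15 (reversed). Taking urolithin A over low in D1 neurons, the value was mitochondrially encoded genes 0.17. For D2 neurons, high over low, the value was mitochondrially encoded genes 0.15. Within D2 neurons, urolithin A over high, the value was mitochondrially encoded genes 0.14. In D2 neurons, urolithin A over low, the values were mitochondrially encoded genes 0.29 and OXPHOS genes 0.0674. For high over low in oligodendrocytes, the value was Mt-nd4l -0.28 (reversed). Taking urolithin A over high in oligodendrocytes, the value was Mt-nd4l 0.0334 (reversed). For oligodendrocytes, urolithin A over low, the value was mitochondrial protein import -0.0203 (reversed). Within oligodendrocyte precursors, urolithin A over high, the values were mitochondrially encoded genes -0.15 (reversed), Mt-atp6 -0.23 (reversed), Mt-co3 -0.0091 (reversed) and Mt-nd4 -0.0609 (reversed). Shares in low anxiety were D1 neurons 30.2%, D2 neurons 24.5%, GABAergic interneurons 5.94%, eccentric neurons 9.52%, microglia 2.91% and oligodendrocytes 9.41%. Shares in high anxiety were D1 neurons 19.8%, D2 neurons 17.7%, GABAergic interneurons 5.54%, astrocytes 5.85%, glutamatergic neurons 7.29%, oligodendrocytes 17.9% and oligodendrocyte precursors 5.17%. Shares in urolithin A were D1 neurons 24.9%, D2 neurons 17.4%, GABAergic interneurons 7.89%, astrocytes 6.45%, committed precursors 1.27%, eccentric neurons 5.78% and oligodendrocytes 21.1%. A filter on the mitochondrial share selects nuclei on that share by construction, and beyond this the cause was not tested.

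With a minimum of 200 UMIs, D1 neurons had 80 higher and 91 lower (high over low), 35 higher and 27 lower (urolithin A over high), 89 higher and 31 lower (urolithin A over low), 16 opposed. D2 neurons had 57 higher and 63 lower (high over low), 50 higher and 22 lower (urolithin A over high), 69 higher and 30 lower (urolithin A over low), 11 opposed. Astrocytes had 6 higher and 29 lower (high over low), 7 higher and 8 lower (urolithin A over high). Oligodendrocytes had 49 higher and 15 lower (high over low), 0 higher and 6 lower (urolithin A over high). Oligodendrocyte precursors had 4 higher and 14 lower (high over low), 11 higher and 2 lower (urolithin A over high). Microglia had 15 higher and 15 lower (high over low), 1 higher and 1 lower (urolithin A over high). In D1 neurons, high over low, the value was mitochondrial ribosome 0.0181 (reversed). For high over low in oligodendrocytes, the value was potassium channels 0.0429 (reversed). Taking urolithin A over low in oligodendrocytes, the value was potassium channels 0.028 (reversed). Fewer genes were measured by construction.

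With a minimum of 30 UMIs, D1 neurons had 454 higher and 451 lower (high over low), 300 higher and 197 lower (urolithin A over high), 490 higher and 278 lower (urolithin A over low), 171 opposed. D2 neurons had 382 higher and 505 lower (high over low), 372 higher and 161 lower (urolithin A over high), 467 higher and 312 lower (urolithin A over low), 172 opposed. Astrocytes had 268 higher and 360 lower (high over low), 152 higher and 255 lower (urolithin A over high). Oligodendrocytes had 463 higher and 283 lower (high over low), 137 higher and 252 lower (urolithin A over high). Oligodendrocyte precursors had 287 higher and 159 lower (high over low), 207 higher and 161 lower (urolithin A over high). Microglia had 411 higher and 134 lower (high over low), 88 higher and 293 lower (urolithin A over high). For D1 neurons, high over low, the value was mitochondrially encoded genes 0.48. More genes with few counts were measured by construction.

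With means over nuclei, within D1 neurons, high over low, the value was mitochondrially encoded genes 0.41. In D1 neurons, urolithin A over high, the value was mitochondrially encoded genes 0.0583. For urolithin A over high in D2 neurons, the value was mitochondrially encoded genes 0.28, and the cause was not tested.

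With the largest subcluster alone, D1 neurons had 60 higher and 29 lower (urolithin A over high), 25 opposed. D2 neurons had 92 lower (high over low), 53 higher and 24 lower (urolithin A over high), 16 opposed. Taking high over low in D1 neurons, the values were mitochondrially encoded genes 0.49, Ppargc1a -0.0276 (reversed) and Oprd1 -0.47 (reversed). For D1 neurons, urolithin A over high, the values were OXPHOS genes -0.0056 and Oprd1 0.0913 (reversed). Within D1 neurons, urolithin A over low, the value was postsynaptic density and adhesion -0.0673. In D2 neurons, urolithin A over high, the values were mitochondrially encoded genes 0.41 and Tac3 -0.59 (reversed). For urolithin A over low in D2 neurons, the value was postsynaptic density and adhesion -0.0779, and the cause was not tested.

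With doublets left in, astrocytes had 80 higher and 172 lower (high over low), 28 higher and 49 lower (urolithin A over high). Oligodendrocyte precursors had 46 higher and 17 lower (high over low), 13 lower (urolithin A over high). Microglia had 43 lower (high over low), 6 higher and 41 lower (urolithin A over high). Taking urolithin A over high in D1 neurons, the values were OXPHOS genes 0.16 and Apoe 0.15 (reversed). For D1 neurons, urolithin A over low, the value was OXPHOS genes 0.15. Within astrocytes, urolithin A over high, the value was glutamate receptors 0.0179 (reversed), and the cause was not tested.

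With a cluster resolution of 0.5, in D1 neurons, urolithin A over high, the values were OXPHOS genes 0.17 and Apoe 0.15 (reversed). For urolithin A over low in D1 neurons, the values were OXPHOS genes 0.16 and postsynaptic density and adhesion -0.047, and the cause was not tested.

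With an equal subcluster mix, D2 neurons had 23 lower (urolithin A over high). Taking urolithin A over high in D1 neurons, the value was Grm8 0 (reversed), and the cause was not tested.

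With median-of-ratios size factors, for D1 neurons, urolithin A over low, the value was postsynaptic density and adhesion -0.0483, and the cause was not tested.

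With TMM factors, microglia had 28 higher (high over low). Within D1 neurons, urolithin A over low, the value was postsynaptic density and adhesion -0.0539. In D2 neurons, urolithin A over low, the value was postsynaptic density and adhesion -0.0717, and the cause was not tested.

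With counts thinned to the smallest total, astrocytes had 17 higher (high over low). Oligodendrocytes had 56 higher (high over low), 7 higher (urolithin A over high). Microglia had 21 higher (high over low), 2 lower (urolithin A over high). Thinning leaves fewer genes measured by construction.

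With no nucleus filter, for urolithin A over low in astrocytes, the values were presynaptic vesicle release 0.0127 (reversed) and potassium channels 0.0169 (reversed). Taking high over low in oligodendrocytes, the value was potassium channels 0.0627 (reversed). For oligodendrocytes, urolithin A over high, the value was mitochondrially encoded genes 0.0317 (reversed). Within oligodendrocytes, urolithin A over low, the value was mitochondrially encoded genes 0.29 (reversed). Shares in low anxiety were neuroblasts 2.19% and oligodendrocytes 17.9%. Shares in high anxiety were neuroblasts 3.99% and oligodendrocytes 24.5%. Shares in urolithin A were D1 neurons 20.5%, neuroblasts 0.414% and oligodendrocytes 23.8%, and the cause was not tested.

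With shares taken among neurons, shares in low anxiety were D1 neurons 39.5%, D2 neurons 29.2%, GABAergic interneurons 4.3%, cholinergic interneurons 0.787%, eccentric neurons 19%, glutamatergic neurons 5.19% and neuroblasts 2.05%. Shares in high anxiety were D1 neurons 34.1%, D2 neurons 26.4%, GABAergic interneurons 5.93%, cholinergic interneurons 0.936%, eccentric neurons 16.4%, glutamatergic neurons 10.3% and neuroblasts 5.88%. Shares in urolithin A were D1 neurons 44%, D2 neurons 31.2%, GABAergic interneurons 8.14%, cholinergic interneurons 1.52%, eccentric neurons 13.6% and glutamatergic neurons 1.23%. The smaller total raises each share by construction.

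With a cluster resolution of 2, the share in low anxiety was eccentric neurons 8.97%. The share in high anxiety was eccentric neurons 6.5%. The share in urolithin A was eccentric neurons 5.58%, and the cause was not tested.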

Other observations

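No tests were run in this part, and Psap and the genes that name clusters were chosen only after the results were seen.

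RT1-T24-3, a class I gene of the rat major histocompatibility complex, was higher in high anxiety than in low anxiety in all 6 classes compared. Its log2 ratios were 0.98 in D1 neurons, 0.89 in D2 neurons, 1.19 in astrocytes, 1.13 in oligodendrocytes, 1.37 in oligodendrocyte precursors and 0.46 (0.00 to 0.94) in microglia. Under urolithin A against high anxiety they ran from -0.47 in astrocytes to -0.00 in D1 neurons. Psap, which encodes the lysosomal precursor prosaposin, was lower in high anxiety in all 6 classes, by -0.82 to -0.59.

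Cluster 10 joined the neuropeptide gene Crh, the galanin receptor gene Galr1, the secreted phosphoprotein gene Spp1 and the vesicular glutamate transporter gene Slc17a6 among its 10 leading genes. Cluster 12 also stayed without a name by the naming rule, with 57, 57 and 76 nuclei in low anxiety, high anxiety and urolithin A. Its highest list was that of D2 medium spiny neurons, at a mean log2 fold of 1.69, against 0.973 in cluster 7, which took that name. Cluster 26, led by Shisa8, held 16, 2 and 1 nuclei. Other small clusters without a name were led by vessel genes such as Flt1, Vtn and Rgs5, and by Igfbp5 and Vim. Among interneurons, 1 cluster was led by Npy, Sst and Nos1, another by Vip and Trh, and a further one by Pthlh and Kit, as known for the main interneuron types of the striatum.

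Median nuclei showed the same order of mitochondrial share as the class sums in 5 of 6 classes: 0.598%, 0.831% and 0.898% in D1 neurons, 0.519%, 0.688% and 0.893% in D2 neurons, and 0.845%, 0.514% and 0.427% in astrocytes of low anxiety, high anxiety and urolithin A. Oligodendrocytes had 1.60%, 1.46% and 1.14%, and microglia 0.898%, 0.499% and 0.537%. The order differed in oligodendrocyte precursors, with 1.01%, 0.623% and 0.881% in median nuclei against 1.12%, 0.689% and 1.16% in class sums.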
